A study of Mus musculus with 4 samples.

How the data were processed

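Gene expression was measured in mouse aortic endothelial cells of the C57BL/6J strain on 4 Affymetrix Mouse Gene 1.0 ST arrays, which summarise each transcript cluster (a group of probes along one gene) as a single value. The labels give 2 arrays of wild type cells and 2 arrays of cells overexpressing human catalase (hcatTg), each from an independent RNA sample. Per the labels' protocols, cells at 80% confluence were kept without serum for 12 h and then cultured in medium with 10% fetal bovine serum for 12 h. Whether the RNA samples came from separate animals is not given in the sources used here, so p-values measure the spread between these RNA samples.

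The deposited value table holds log2 values for 35557 transcript clusters on the 4 arrays. Affymetrix Expression Console is named in the submitters' processing notes, and the version, probe annotation and genome build are not given in the sources used here. The array medians were 5.75 and 6.02 for wild type replicates 1 and 2, and 5.40 and 6.00 for hcatTg replicates 1 and 2, so the arrays had not been brought to one distribution. The scale was taken as log2 because the difference between the second arrays equals the log2 of the authors' second fold to within 9e-05 for all 398 probe sets of their table. Array data have no read depth, and the number of arrays limits the precision.

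The authors' deposited table lists 398 probe sets with gene names, log2 RMA signals (robust multi-array average, per the file headers), a linear ratio, and signed fold changes of hcatTg over wild type at a first time, a second time and on average. A negative fold in that table stands for wild type over hcatTg. Every listed probe set differed at least 2-fold in one direction at both times, the smallest absolute fold being 2.00, so the table was selected on these same arrays and is not independent evidence. The first-time signals were on another normalization than the value table: the log2 fold differed by a median of 0.129 and by up to 1.05. Names were taken only from this table. Through its accessions, 385 names were matched to the RefSeq gene table of mouse, 41 of them to another symbol than the file's, and 13 were kept from the file.

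The test fixed before the data were examined was limma (version 3.58.1, in R 4.3.3; lmFit and eBayes) on the deposited values, hcatTg minus wild type, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. It was planned with 1 cluster per gene symbol. A platform annotation was not used here, so all 35557 clusters were tested, a unit listed in advance as an alternative. Control rows could not be told apart by name and stayed in. Further planned items not run for the same reason were the level of the mouse Cat cluster, the mean over the clusters of a gene, and the tests of whole gene lists (camera, cameraPR and fry). A count at an unadjusted p below 0.05 and at least 1.5-fold was fixed as a description. With 2 arrays against 2, an exact two-sided permutation test cannot go below p = 0.333.

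The named genes follow a rule written in advance: the 12 largest rises and the 12 largest falls past the threshold with both hcatTg arrays on one side of both wild type arrays. Open places were filled by the largest folds at an unadjusted p below 0.01 with separated groups. Up to 4 members per list with the smallest p were added. Because names came from the authors' table, only its genes could be named. Further genes outside the rule are marked where they appear. The 25 gene lists were also fixed in advance. Their members were counted within the authors' table, and Fisher's exact test (two-sided) compared their directions with the rest of the table for the 4 lists with at least 5 members there, adjusted over those 4.

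The authors' table compares the first arrays of the genotypes at one time and the second arrays at another, so the replicate numbers were taken to pair the samples. In the value table, deviations of same-time arrays from their group means correlated at r = 0.689 across clusters, which are not independent replicates. A fit with the replicate number as a block was planned as an alternative, with intensity trend, robust eBayes, array weights, quantile normalization, median centring, filters on level, leaving out each array, a two-sample test without moderation, and a threshold of 0.1. In all, 24 fits were run and 10 of them were chosen after seeing the data. Those 10 combined the block with a normalization, tested only the named clusters, or left out the 6636 clusters numbered below the first named one. That last choice followed the finding that wild type replicate 1 stood apart there. Whether those clusters hold the control rows of the array could not be checked without the platform annotation.

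The fits were tested on simulated data for 35557 clusters, of which 200 were changed, with spreads drawn from each fit's own variance prior. This replaced an earlier simulation, with noise from each cluster's own residual spread, in which no fit called any changed cluster. At the spread of the unblocked fit, 2% of clusters changed by 2 log2 units, 92% of those changed by 4 and 100% of those changed by 6 were called. At the spread of the median-centred blocked fit, and with the time differences of the pairs, the unblocked fit called 0%, 78% and 90%. Both the spread and the time differences changed there. Over 10 draws at the spread of the unblocked fit, without time differences, a median of 5.62% of its calls were false, against a nominal 5%. Those draws follow the variance model that the fit assumes, so they do not show its false share on these paired arrays. At the spread of the centred blocked fit without the lowest-numbered clusters, a blocked fit on all 35557 simulated clusters called 94% of those changed by 1 log2 unit. A median of 17.6% of its calls were false, with a range of 1.99% to 34.5%, against the same nominal 5%. The prior degrees of freedom estimated in those draws ranged from 9.19 to 313, and the cause of the excess was not tested.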

Results

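Expression profiles were compared between wild type mouse aortic endothelial cells (2 arrays) and hcatTg cells, which overexpress human catalase, an enzyme that breaks down hydrogen peroxide (2 arrays). All cells had been rested without serum for 12 h and given serum for 12 h. The comparison addresses which transcripts differ between hcatTg and wild type cells. Sex-linked genes also separated the genotypes, as given below, so differences cannot be assigned to catalase or to sex. Across clusters, Pearson's r was 0.969 between the first arrays and 0.984 between the second arrays of the genotypes, 0.950 between the wild type arrays and 0.973 between the hcatTg arrays. Transcript clusters are not independent replicates, and these values describe the arrays only.

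Xist, the noncoding RNA that silences one X chromosome in female cells, rose by 6.21 ± 0.504 log2 units (SE, n = 2 arrays per genotype; limma, adjusted p = 0.0117) in hcatTg cells. Its level was 4.68 ± 0.0374 in wild type and 10.89 ± 0.792 in hcatTg (SD, n = 2). Ddx3y, a Y-linked RNA helicase gene, fell by 5.35 (SE 0.551, limma adjusted p = 0.0333), from 9.67 ± 0.813 to 4.32 ± 0.668 (SD, n = 2). Pcolce2, which encodes an enhancer of procollagen processing, fell by 4.94 (SE 0.448, limma adjusted p = 0.0157), from 9.53 ± 0.198 to 4.59 ± 0.267 (SD, n = 2). These were the 3 clusters of 35557 that passed the limma test on the deposited values, 1 higher and 2 lower. After quantile normalization or median centring, which move the median difference of all clusters from -0.18 to about 0.00, limma called 0 clusters, with 1253 and 975 at an unadjusted p below 0.05. With the replicate number as a block it called 1161, falling to 24 with median centring and 0 with quantile normalization, where 4189 had an unadjusted p below 0.05. In every blocked fit each cluster has 1 residual degree of freedom, so its variance rests largely on that of all clusters together. The blocked fit on the deposited values estimated infinite prior degrees of freedom, so all clusters shared a single variance. Its p-values therefore follow only the size of the mean difference, not how closely the times matched for a gene.

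The count also depended on which clusters and arrays entered. Among clusters whose other 3 arrays lay within 1 log2 unit of each other, wild type replicate 1 lay at least 4-fold below them in 252, and 244 of these were among the 6636 lowest-numbered clusters, none of which the authors' table names. Without those clusters, a choice made after seeing the data, limma called 52, and 1554 with median centring and the block. Xist, Ddx3y and Pcolce2 were among the calls of both fits. With the spread of the second of these fits simulated on all clusters, the median share of false calls exceeded the nominal share. Without wild type replicate 1 limma called 103 clusters, without wild type replicate 2 it called 192, and without either hcatTg array it called 0.

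At an unadjusted p below 0.05 and at least 1.5-fold, 643 clusters differed, 171 higher and 472 lower in hcatTg. That is fewer than the 1778 that the p alone would give by chance, but this fit counts the difference between times as spread. With the replicate block, 3356 clusters had an unadjusted p below 0.05, and 4211 and 4189 with median centring or quantile normalization added. The comparison with chance thus depends on the pairing. The split depended on scale: it was 499 higher and 735 lower after quantile normalization, and 410 and 565 after median centring. It also turned with single arrays: it was 735 higher and 192 lower without wild type replicate 2, and 304 and 136 without hcatTg replicate 1. It was 81 and 940 without wild type replicate 1, and 81 and 1259 without hcatTg replicate 2. With the replicate block, which keeps the same-time pairs, it was 850 higher and 2506 lower.

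Among genes higher in hcatTg that did not pass the test, the largest differences were those of Igfbp6, which encodes an insulin-like growth factor binding protein (4.27 ± 0.753 log2 units, SE, limma adjusted p = 0.256), Tnfsf15, an endothelial cytokine gene (4.13), and Pgr, the progesterone receptor gene (4.13). Npy1r, a neuropeptide Y receptor gene, was higher by 3.46 at the first time and 4.54 at the second (limma adjusted p = 0.105). Dlk1, an imprinted gene for a Delta-like membrane protein, was higher by 3.86 ± 0.468 (SE, limma adjusted p = 0.0819). Angpt2 (3.78), Pi15 (3.60), Thbs2 (3.41), Slfn3 (3.14), Aldh1a2 (3.05) and Mmp2 (3.01) followed, and Slfn3 belongs to a family of similar copies that probes may share. The size of some differences was unequal at the 2 times: Pgr was higher by 2.70 at the first and 5.56 at the second, and Aldh1a2, a retinoic acid synthesis gene, by 1.41 and 4.70. Tnfsf15 lay at 7.89 and 11.21 on hcatTg arrays 1 and 2, against 5.42 ± 0.271 in wild type (SD, n = 2).

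Among genes lower in hcatTg that did not pass the test, Gpm6a, a membrane glycoprotein gene, differed by -4.49 ± 0.668 log2 units (SE, limma adjusted p = 0.147). Tenm3, a teneurin gene, differed by -4.04 ± 0.485 (SE, limma adjusted p = 0.0819). C4bp (-4.03), a complement regulator gene, Crip2 (-3.82), Adamts9 (-3.59), Tcf21 (-3.58), Peg3 (-3.58) and Il33 (-3.53) followed. Tcf21 encodes a mesodermal transcription factor, Peg3 is an imprinted zinc finger gene, and Il33 encodes an alarmin cytokine. Of the 24 genes named by the rule, 3 passed limma on the deposited values and 24 with the replicate block, which leaves in a median shift of -0.37 between the first arrays. With the block, 11 passed after median centring and 0 after quantile normalization, while the differences stayed about as large: 6.36 for Xist, 4.48 for Igfbp6 and -4.78 for Pcolce2 after quantile normalization. Without the lowest-numbered clusters, 23 passed with no block, and 24 with the block after either normalization. These genes were picked for large differences on these same arrays, so the counts describe the fits only.

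**Figure D1:**
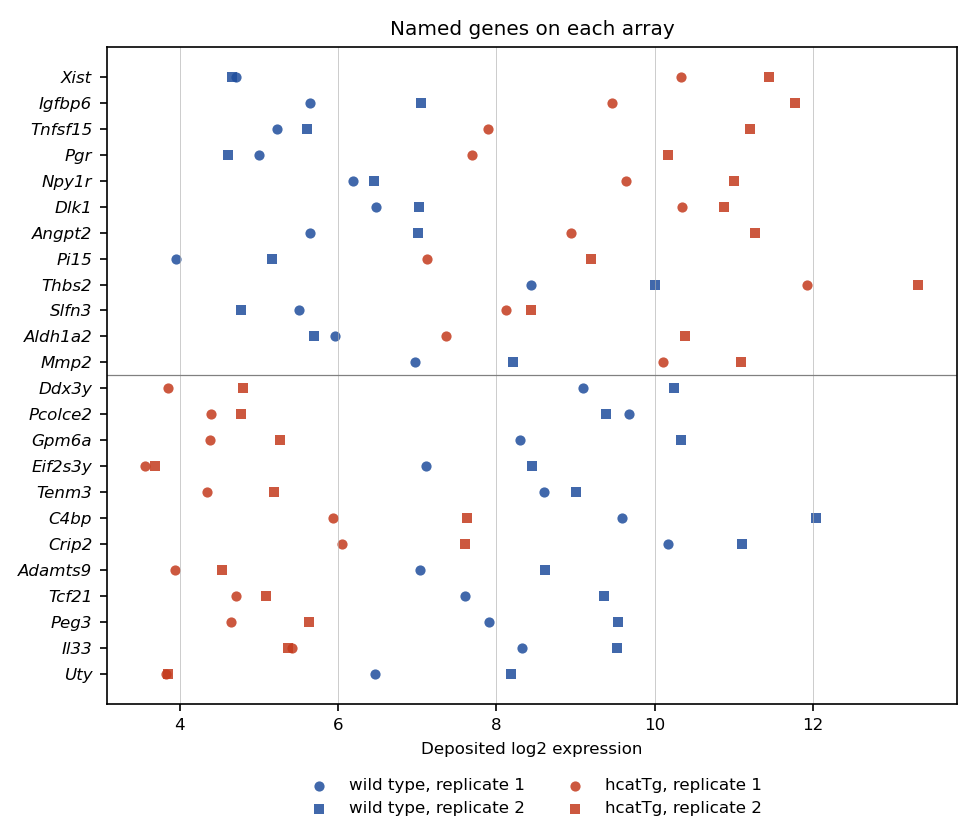
Deposited log2 expression (horizontal axis) of the 24 genes named by the rule, one row per gene and one point per array, with the 12 higher genes above the line and the 12 lower genes under it. Both hcatTg arrays lie on one side of both wild type arrays for each gene, and Xist is near 4.68 in wild type and 10.89 in hcatTg.

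The 5 sex-linked genes on the fixed list separated the genotypes on every array. Beside Xist and Ddx3y, the Y-linked genes Eif2s3y (-4.15 ± 0.531 log2 units, SE, limma adjusted p = 0.0886), Uty (-3.49 ± 0.585, adjusted p = 0.214) and Kdm5d (-2.47 ± 0.505, adjusted p = 0.429) were lower in both hcatTg arrays, Kdm5d being named outside the rule after its values were seen. Xist lay at percentiles 26.4 and 25.7 of all clusters on the wild type arrays and at 95.9 and 96.4 on the hcatTg arrays. Ddx3y lay at 89.4 and 91.9 on the wild type arrays and at 18.3 and 28.2 on the hcatTg arrays. Signal over background was not analysed here, so the lower level of each gene is not shown to be above background and the sizes of these differences hold for the deposited values only. This sex-linked difference runs along the genotype comparison, so it accompanies every gene group given here.

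At least 2-fold differences in one direction at both times, a count added after seeing the data and with no test, were found in 553 clusters, 134 higher and 419 lower in hcatTg, against 28 that went in opposite directions. With median centring there were 178 higher and 267 lower, and with quantile normalization 181 higher and 282 lower. The authors' deposited table names 398 probe sets, 93 higher and 305 lower, and 350 of them are among the 553. The genotype differences at both times correlated at r = 0.378 across all clusters. Without the 6636 lowest-numbered clusters r was 0.593 after median centring and 0.635 after quantile normalization, and it was 0.527 over the clusters above the median level.

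**Figure D2:**
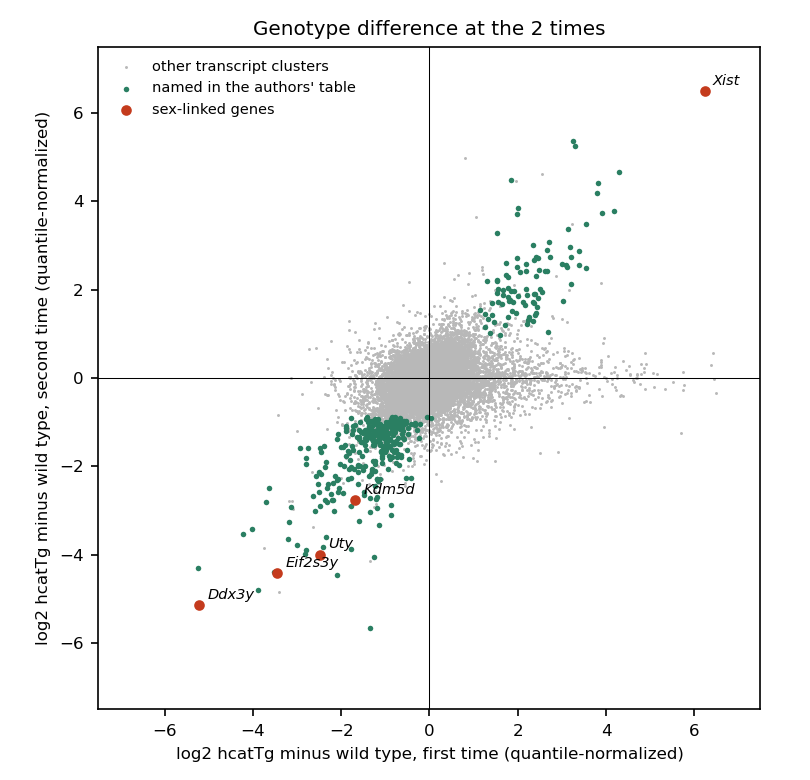
Quantile-normalized log2 difference, hcatTg minus wild type, at the first time (horizontal axis) and at the second (vertical axis), one point per transcript cluster, with genes of the authors' table and the 5 sex-linked genes marked. After quantile normalization 463 clusters differed at least 2-fold in one direction at both times and 29 in opposite directions.

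Of the 25 fixed gene lists, 12 had a member in the authors' table. Because that table was selected on these arrays, the counts describe it and are not independent evidence of direction, and absence from it does not show that a gene was unchanged. For the same reason no count adjusted over the list alone is given. Passing a blocked fit also says little about a list. Of the 398 probe sets, 378 passed with the replicate block, and 19 with median centring added. Without the lowest-numbered clusters, 395 passed with block and centring, and 361 with block and quantile normalization. The calls given below for each list are to be read against these counts. None of the 4 lists tested differed in direction from the rest of the table by Fisher's exact test: adjusted p = 1 for NF-kB genes, 0.572 for fibroblast and extracellular matrix genes, 1 for angiogenesis genes and 1 for sex-linked genes. Since 305 of the 398 were lower, lists this short could hardly show an excess of lower genes, so no likeness of direction follows. The sex-linked list joins Xist with Y-linked genes of opposed direction, so its test says nothing on direction. Outside the sex-linked list, no list member passed limma on the deposited values.

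Of the 32 NF-kB and endothelial inflammatory genes, 8 were in the table, 1 higher and 7 lower in hcatTg. The chemokine gene Ccl2 differed by -2.07 ± 0.520 log2 units (SE, limma adjusted p = 0.923) and the cytokine gene Il6 by -2.62 ± 0.670 (SE, limma adjusted p = 0.960). Ccl7 differed by -2.19, while Ptgs2, the inducible cyclooxygenase gene, was higher by 1.95 ± 0.463 (SE, limma adjusted p = 0.777). All 8 passed with the planned replicate block and 0 with median centring added, where Il6 differed by -2.44 and Ccl2 by -1.89. Without the lowest-numbered clusters, 8 passed with block and centring, and 7 with block and quantile normalization.

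Of the 35 genes on the antioxidant list, 3 were in the table, and all were lower in hcatTg. They were the metallothionein genes Mt2 (-2.70 ± 0.874 log2 units, SE, limma adjusted p = 1.00) and Mt1 (-1.47), which do not encode enzymes, and the methionine sulfoxide reductase gene Msrb1 (-1.25). For Mt1 and Msrb1 the values of the genotypes overlapped, though hcatTg was lower at both times. Catalase itself, Cat, is not among the named probe sets, and its level was not analysed here. The aryl hydrocarbon receptor gene Ahr was higher by 1.77 ± 0.803 (SE, limma adjusted p = 1.00), and its values overlapped between the genotypes too. With the planned replicate block, Mt2, Mt1, Msrb1 and Ahr passed (limma adjusted p = 8.6e-14, 0.00059, 0.00709 and 8.79e-06), and with median centring added none of them did (0.108, 0.125, 0.140 and 0.151). Without the lowest-numbered clusters they passed with the block after either normalization. The blocked p-values on the deposited values follow only the size of the difference, since all clusters shared a single variance. The list of NADPH oxidases and other oxidant sources had 1 member in the table, Ptgs2. NRF2 target genes, peroxisome genes and interferon response genes had 0 members there, as did the lists for G1/S, G2/M, CDK inhibitors and p53, immediate-early genes, lymphatic and adipocyte markers, unfolded protein response, cholesterol, the respiratory chain and apoptosis.

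Of the 35 angiogenesis, TGF-beta and BMP genes, 8 were in the table, 2 higher and 6 lower. Angpt2, a ligand of the Tie2 receptor, was higher by 3.78 ± 0.752 log2 units (SE, limma adjusted p = 0.403), while Vegfc, a lymphangiogenic growth factor gene, differed by -2.52 ± 0.522 (SE, limma adjusted p = 0.429). Tgfb3 differed by -2.23 and the Notch ligand gene Jag1 by -1.92. With the replicate block 7 of the 8 passed, and 1 with median centring added, where Vegfc differed by -2.34 and Tgfb3 by -2.05. Without the lowest-numbered clusters, 8 passed with block and centring, and 7 with block and quantile normalization. Both hypoxia list members in the table, Epas1 (-1.41) and Vegfa (-0.98), were lower, though the values of the genotypes overlapped for Vegfa. With the replicate block 1 of them passed, and 0 with median centring added. Without the lowest-numbered clusters, 2 passed with block and centring, and 1 with block and quantile normalization.

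Markers of other cell types went both ways. All 4 smooth muscle markers in the table were lower: Rgs5 (-2.92 ± 0.898 log2 units, SE, limma adjusted p = 1.00), Cnn1 (-2.39), Actg2 (-2.14) and Lmod1 (-0.95). Of the 4 mesothelial and epithelial markers, Msln (2.51 ± 0.439, SE, limma adjusted p = 0.245) and Upk1b (2.76) were higher, and Upk3b (-2.68) and Wt1 (-1.35) were lower. Of 6 fibroblast and matrix genes, 3 were higher, among them Mmp2 and Thbs2, and 3 were lower, among them Fbln1 (-2.15) and Col5a1 (-1.21). Of the macrophage and leukocyte markers, Cd53 was higher by 2.46, and Lcp1 (-2.33) and Lyz2 (-1.88) were lower. The endothelial receptor gene Kdr was higher by 2.31 ± 0.603 (SE, limma adjusted p = 1.00), and Eng, a TGF-beta co-receptor gene, differed by -1.31 ± 0.460 (SE, limma adjusted p = 1.00). On wild type arrays 1 and 2, Kdr lay at 5.63 and 4.67, below the array medians of 5.75 and 6.02. Eng lay above these medians, at 9.57 and 10.15. With the planned replicate block, 3 of the 4 smooth muscle markers passed, as did the 4 mesothelial, 6 fibroblast, 3 macrophage and 2 endothelial markers in the table. With median centring added, 1 mesothelial and 1 fibroblast marker passed and 0 of the others, where Rgs5 differed by -2.74, Cnn1 by -2.21 and Kdr by 2.49. Without the lowest-numbered clusters, block and centring called 4 smooth muscle, 4 mesothelial, 6 fibroblast, 3 macrophage and 2 endothelial markers. Block and quantile normalization called 2 of the smooth muscle markers and all those of the other types in the table.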

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

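The limma count of 3 changed clusters was not stable, and the causes were not tested except where a setting leaves out clusters or arrays. Among planned settings, robust eBayes, array weights and leaving out clusters below the median level gave 2 each, an intensity trend 42, a threshold of 0.1 gave 8, the replicate block 1161, and the authors' deposited table lists 398. Quantile normalization, median centring, leaving out the clusters of lowest level and a two-sample test without moderation gave 0, with 1253, 975, 393 and 569 clusters at an unadjusted p below 0.05. Leaving out one array gave 0 to 192: 103 and 192 without wild type replicates 1 and 2, and 0 without hcatTg replicate 1 or 2 (440 and 1340 at an unadjusted p below 0.05). The lone array is then assumed to vary like the other group. The other settings were chosen after seeing the data. Testing only the named clusters gave 65, the replicate block with median centring 24, with quantile normalization 0 (4189 at an unadjusted p below 0.05) and with quantile normalization and trend 50. Leaving out the 6636 lowest-numbered clusters gave 52, with quantile normalization 1, with the replicate block 908, with block and median centring 1554, with block and quantile normalization 951, and without wild type replicate 1 as well 119. The adjusted p of Xist ranged from 1.25e-110 to 1, of Ddx3y from 6.43e-82 to 1 and of Pcolce2 from 5.66e-70 to 1. The looser count of 643 was 295 with the two-sample test without moderation, 955 with an intensity trend, 1234 with quantile normalization, 975 with median centring, 393 and 299 with the filters on level, 3356 with the replicate block, and 440 to 1340 without one array. In the added settings it was 156 for named clusters, then 2491, 2184 and 2278 with the block and centring, quantile normalization, or quantile normalization and trend. Without the lowest-numbered clusters it was 1029 with quantile normalization, 2223 with the block, 1677 with block and centring and 1608 with block and quantile normalization. The count of 553 clusters at least 2-fold at both times was 90 at 4-fold. Of the 63 genes named in the text, 1 changed direction: Saa3 differed by -2.46 log2 units with all arrays and by -4.98 to 0.0643 without one array, the ends being without wild type replicate 1 and 2. The tests of whole lists, of Cat and of the mean over clusters of a gene were not run. Arrays limit the precision through their number, and signal over background was not analysed here.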

Other observations

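The tests of explanations in this part were chosen after the result was seen, except the odds ratio for X-linked genes. The genes in this paragraph were chosen after their values were seen, and none passed limma on the deposited values. Beside Pgr, the estrogen receptor gene Esr1 (2.10 ± 0.565 log2 units, SE) and the estrogen-responsive gene Greb1 (2.81 ± 0.666) were higher in both hcatTg arrays. Among imprinted genes picked by hand, the Dlk1 neighbour Gtl2 (2.01) and H19 (1.12) were higher, and Peg10 (-2.46), Dio3 (-3.01) and Grb10 (-1.55) were lower. Dlk1, Gtl2 and Dio3 belong to one imprinted region.

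For 3 genes picked by hand, the arrays of wild type lay far apart. Lcn2 was at 5.67 in wild type replicate 1 and 10.58 in replicate 2, and had a mean of 4.30 in hcatTg. Saa3 was at 5.48 and 10.52 in wild type and at 3.98 and 7.10 in hcatTg. Serpina3n was at 6.92 and 10.70 in wild type and at 4.72 and 6.04 in hcatTg. Saa3 thus also differed between the hcatTg arrays, and without wild type replicate 2 its genotype difference was 0.0643 log2 units.

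Sex-linked genes separated the genotypes. A single mislabelled array is argued against, since 0 of the 5 genes had an array nearer to the other genotype than to its own. A difference in scale between arrays is argued against too, since the smallest gap between any hcatTg and any wild type array was 1.68 log2 units after quantile normalization, above the shift of any array pair. Xist was higher and the 4 Y-linked genes were lower on both hcatTg arrays than on both wild type arrays. Female hcatTg cells and male wild type cells would give this pattern. That the cells of the genotypes came from animals of opposite sex stays open as a hypothesis. The value it needs, 5 of the 5 genes at least 2-fold apart in opposed directions, restates the pattern and adds no separate support. Sex is not in the labels, and with genotype and this pattern fully aligned, differences in other genes cannot be assigned to catalase or to sex.

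More clusters were lower than higher in hcatTg with all 4 arrays, but not without wild type replicate 2 (735 higher and 192 lower at an unadjusted p below 0.05 and 1.5-fold) or without hcatTg replicate 1 (304 and 136). Leaving out an array breaks a same-time pair, so these counts also carry the difference between times. With the pairs kept, the replicate block gave 850 higher and 2506 lower at that limit. Array scale may account for part of it: after quantile normalization 60.9% of the clusters at least 2-fold at both times were lower, against 75.8% as deposited, and 60% with median centring. At 4-fold the shares were 55.4% and 50%, against 67.8% as deposited. Both normalizations act on the balance itself, so the excess cannot be told apart from scale. The excess in the authors' table was not confined to X-linked genes. Leaving out the 5 sex-linked genes, 76.8% of its 370 autosomal genes were lower (95% exact interval 72.1 to 81.0). Among those at least 2-fold at both times after quantile normalization the lower ones were 183 of 268, or 68.3% (62.3 to 73.8). These intervals treat genes as independent, and the table was selected on these same arrays. They therefore cannot decide whether X chromosome dosage was the whole cause. The test written in advance gave an odds ratio of 1.10 for being higher among the 20 X-linked genes (Fisher's exact two-sided p = 0.791), and a higher X dosage would not bear on an excess of lower genes.

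Mesothelial and smooth muscle markers differed between genotypes. Whether the hcatTg cultures held fewer mesothelial cells cannot be told. Of the 4 named members, Msln and Upk1b were at least 2-fold higher at both times, and Upk3b and Wt1 were lower. The authors' table was selected at that limit, so any higher member meets it, and these are 4 of 15 markers. Fewer smooth muscle cells remains possible, since 4 of the 4 named members were lower. But these are 4 of 18 markers and were picked for a change by the authors' table. Fewer such cells thus cannot be told apart from a change of expression within the cells. How far the cultures were endothelial was not tested. Of the catalase effect itself, no biological explanation was tested.

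The 4 arrays can be split into pairs in only 3 ways, too few for a share under 0.05. The genotype split gave 3 calls, and 2 of the 3 splits gave as many, the real one included. The crossed split, which like the genotype split parts both pairs of same-time arrays, gave 0 limma calls, with 48 clusters at an unadjusted p below 0.05 and at least 1.5-fold, against 643 for genotype. The highest other split, by time, parts neither pair and gave 5640 on the deposited values, which points to a difference between times on that scale. After quantile normalization the genotype, time and crossed splits gave 0 limma calls, with 1234, 6733 and 130 clusters at that looser limit.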
